A study of Mus musculus with 12 samples.

How the data were processed

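The series holds 6 short-read and 6 long-read samples of nuclei from SNc-VTA and olfactory bulb of 3 mice. Per the labels, frozen brains were sectioned, the regions dissected, and nuclei loaded at 12000 per channel for a target of 7500 on the 10x 5' v2 chemistry, and the same amplified cDNA went to long-read sequencing. The deposited short-read matrices hold UMI counts per gene and nucleus, made with Cell Ranger 6.1.1 per the file headers, for the barcodes that it called as cells. The deposited library summaries give percent values for mapping and saturation, and they show that reads in introns were counted. The processing notes name a human genome build, and no mouse build is stated for the short reads. The deposited long-read table holds read counts of SNCA splice forms per library and cell type. Per its description, the authors basecalled with MinKNOW, aligned to GRCm39 with minimap2, matched barcodes to the short-read cells, and took the cell types from their own clustering. That table covers 4 libraries, since the authors left out both libraries of M9376 after sequencing, so a planned comparison of 3 against 3 became 2 against 2. Its description gives 37 entries, whereas the table holds 38, of which 34 are cell types. Duplicate copies of the matrices, with identical values, were not used here.

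Depth per library, in the order SNc-VTA then olfactory bulb for M9376, M9377 and M9378, was 553675196, 562966145, 641249871, 601508478, 621304645 and 631729471 reads, at saturations of 75.8%, 87.8%, 86.5%, 89.4%, 88.6% and 92.2%. Barcodes were kept with at least 500 genes, under 5% mitochondrial UMIs and a Scrublet score under 0.2 (expected doublet rate 0.06), and doublets made up 9.52%, 5.27%, 5.54%, 3.91%, 3.47% and 4.79%. This left 21708, 7897, 7345, 6026, 6062 and 6812 nuclei. Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 was used. Log values were scaled to 10000 UMIs, and clustering took 3000 variable genes (without SNCA-GR, Snca and mitochondrial genes), 40 principal components, 15 neighbours and the Leiden method (leidenalg 0.10.2, resolution 1, seed 1). Figures were drawn with matplotlib 3.10.9. The 53 clusters were named from fixed markers of 24 classes, asking for 3 markers with a log2 fold over 1 (5 CPM added). Non-neuronal classes also needed a mean log2 fold over 1.5. Neuron-like clusters needed 3 general neuron markers over the named non-neuronal clusters, with no bound on the mean. Kinds of neuron were then named against the other neuron-like clusters, with a lower bound on the mean than for the non-neuronal classes. Clusters with over 90% of nuclei in 1 library, and clusters whose top genes pointed to another class, stayed unnamed. So did a cluster with markers of unrelated classes whose means each exceeded 0.25 of the highest class mean in that cluster. A class was compared where every library held at least 20 of its nuclei, which left out endothelial-like nuclei, with 0, 6 and 9 in the olfactory bulb. The feature tables list 32384 features, and that of the SNc-VTA library of M9377 lacks 1 of them, SNCA-GR. SNCA-GR and Snca were therefore summed in every library, a choice made after seeing the files.

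UMIs were summed per library and class, and genes compared between regions with edgeR 4.0.16 (R 4.3.3; TMM, filterByExpr, quasi-likelihood F test, two-sided) with the mouse as a block, taking a Benjamini-Hochberg adjusted p under 0.05 as passed. The pairing comes from the labels, which give both regions of each animal, and the libraries' deviations from the region means correlated at 0.189, 0.064 and 0.334 within mice. Between different mice these correlations ran from -0.254 to 0.159, so the value within M9377 does not stand out from them. The ± of a log2 difference is the difference divided by the square root of F. CPM means ± SD are over 3 libraries. The interaction of region and class took each library as a block. The shares of nuclei were tested in edgeR over classes and by exact permutation. The 26 fixed gene lists were tested with camera in limma 3.58.1 (preset correlation 0.01), and beside it with an estimated correlation and with fry, and lists needed 3 measured members. The estimated form draws on the few residual degrees of freedom of the libraries, so it could hardly call a list and decides little. The text names members of these lists, class markers, SNCA, and the 10 largest rises and falls among genes that passed with an average log2 CPM of at least 5 and 1 direction in all 3 mice, a rule fixed with the lists and tests before the data were examined. Where a gene had 0 UMIs in a region, its fold is given as a lower bound from a floor of 3 UMIs over the group, and with 1 to 3 UMIs as a ratio with a 95% counting interval, and these cover counting error only. Gene positions are not given in the files.

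RNA free in the suspension was estimated for each glial class and region from markers of other classes at 20 CPM or more in all nuclei, as the median percent of the all-nuclei level that the class shows. This was 27.2% and 32.4% in astrocyte-like nuclei of SNc-VTA and olfactory bulb, 14.4% and 7.44% in oligodendrocyte-like, 27.6% and 22.8% in precursor-like and 18.0% and 12.3% in microglia-like nuclei, and a gene counted as above it when over 2 times that level in the region where it was higher. Of the markers themselves, 20% to 32.61% also lay above 2 times their median, so the bound does not part the 2 kinds of gene sharply. On simulated counts with 200 changed genes, the fits called 72.7% of genes changed 2-fold over all nuclei (19060 genes), 81.2% in neurons (17909), 41.7% in astrocytes (9571), 43.1% in oligodendrocytes (11837), 44.1% in precursors (6387), 46.9% in microglia (5104) and 21.0% for the interaction (10474), and at most 0.097% of unchanged genes. The simulation held no mouse effect and few changed genes, whereas 11450 genes passed in the data over all nuclei and 10979 in neurons. Its percentages may therefore not hold for those 2 fits. Long-read shares were compared by exact permutation over libraries, by sign-flip within mice and by Fisher's exact test within mice, with Wilson 95% intervals. Alternatives included DESeq2 1.42.0 (size factors, and its Wald test), no low-count filter, no mouse block, each mouse left out, at least 200 or 1000 genes per nucleus, doublets kept, UMI sums and nuclei thinned, Leiden resolutions 0.5 and 2, and for the long reads another denominator and at least 10 reads per isoform.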

Results

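Nuclei were profiled from 2 brain regions of the same 3 male mice, each 55 days old: the substantia nigra pars compacta with the ventral tegmental area (SNc-VTA), which holds the midbrain dopamine neurons, and the olfactory bulb, the forebrain relay of smell. All mice were homozygous for SNCA-GR, a gene replacement in which human SNCA, the gene for alpha-synuclein, takes the place of mouse Snca. Each region of each mouse (M9376, M9377 and M9378) gave 1 droplet library, so that n = 3 per region. The UMI totals of the libraries ran from 28035844 in the olfactory bulb of M9378 to 69446489 in the SNc-VTA of M9376. They were 36567798 and 36126715 in the other olfactory bulb libraries, and 48625956 and 37448462 in the other SNc-VTA libraries. After filtering, 35115 SNc-VTA nuclei and 20735 olfactory bulb nuclei were kept. The SNc-VTA library of M9376 stood apart, with 24430 deposited barcodes against 6511 to 8494 in the others, although the labels give 12000 nuclei loaded. Its median was 1622 UMIs per barcode, against 3132 to 4192 in the others. Per the labels, the brain of M9376 was sectioned a day before the others, for both regions. Long reads of the same cDNA were counted over the SNCA 5' untranslated region, with 2101 and 1765 assigned reads in the SNc-VTA and 3533 and 3380 in the olfactory bulb of M9377 and M9378. The labels name the mouse line, the regions and the paired read types and state no hypothesis. The comparisons below ask how the regions differ in cell classes, in genes and in SNCA transcripts. Values are means ± SD over libraries, and log2 differences are SNc-VTA minus olfactory bulb ± SE. A class named "-like" rests on fixed markers and may differ from the names the study used.

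The regions differed in the classes of nuclei they held. Neuron-like nuclei made up 27.9% ± 12.2 in SNc-VTA and 89.6% ± 1.32 in the olfactory bulb (log2 -1.79 ± 0.43, adjusted p = 6.65e-04). Oligodendrocyte-like nuclei, the myelinating glia, made up 34.3% ± 9.90 in SNc-VTA and 2.03% ± 0.394 in the olfactory bulb (log2 4.05 ± 0.47, adjusted p = 1.86e-07). Astrocyte-like nuclei made up 7.35% ± 3.54 in SNc-VTA and 1.21% ± 0.405 in the olfactory bulb (log2 2.53 ± 0.44, adjusted p = 3.60e-05). In the olfactory bulb of M9377 and M9378 the authors named 231 and 209 nuclei astrocytes, against 87 and 99 astrocyte-like nuclei here. In SNc-VTA they named 595 and 642, against 582 and 641 here. The olfactory bulb share may therefore be too low and the difference too large. Oligodendrocyte precursor-like nuclei made up 2.45% ± 0.937 in SNc-VTA and 0.645% ± 0.0273 in the olfactory bulb (log2 1.83 ± 0.45, adjusted p = 7.27e-04). Committed oligodendrocyte precursor-like, endothelial-like and pericyte-like nuclei also held larger shares of the SNc-VTA, at 1.15%, 0.519% and 0.257% against 0.212%, 0.0772% and 0.00423% (adjusted p = 1.74e-04, 1.37e-04 and 3.60e-05). The pericyte-like share of the olfactory bulb rests on 1 nucleus. In the SNc-VTA of M9377 and M9378 the authors named 124 and 259 nuclei endothelial, against 34 and 51 endothelial-like nuclei here. The endothelial-like share of SNc-VTA may therefore be too low. Olfactory ensheathing-like nuclei, the glia that wrap the olfactory axons, made up 2.61% ± 1.18 of the olfactory bulb and 0 of 35115 SNc-VTA nuclei, which allows a share of up to 0.00854%. Fibroblast-like nuclei were the smaller share in SNc-VTA, at 0.149% ± 0.101 in SNc-VTA and 0.495% ± 0.265 in the olfactory bulb (log2 -1.70 ± 0.51, adjusted p = 0.00377). Microglia-like nuclei made up 3.18% ± 0.560 in SNc-VTA and 1.87% ± 0.372 in the olfactory bulb and did not pass (log2 0.77 ± 0.43, adjusted p = 0.0864). With named nuclei alone as the denominator, chosen after seeing the data, the share was larger and passed (adjusted p = 1.92e-05). With TMM over classes, an alternative planned before, it was smaller and also passed (log2 -0.79, adjusted p = 0.00278), so its direction depends on the scaling. In an exact permutation test, two-sided, each of these shares gave p = 0.1, the smallest that 3 against 3 allows, except that of the fibroblast-like nuclei (p = 0.2). The edgeR test called 9 of 10 classes, 6 larger and 3 smaller in SNc-VTA. In the SNc-VTA of M9376, 54.5% of nuclei stayed unnamed, against 6.68% and 6.89% in M9377 and M9378. This lowers the shares of all named classes of that library.

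**Figure D1:**
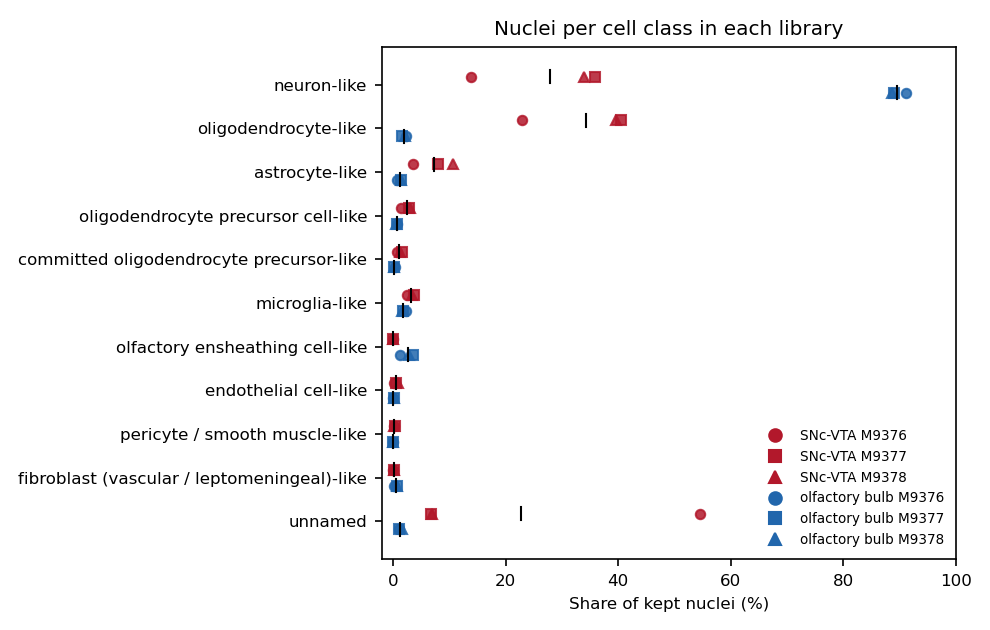
Share of kept nuclei (percent, horizontal axis) in each cell class, with 1 point per library (colour for the region, shape for the mouse) and a bar at the mean of each region. Neuron-like nuclei form the largest share of every olfactory bulb library, and oligodendrocyte-like nuclei hold a mean of 34.3% in SNc-VTA against 2.03% in the olfactory bulb.

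Over all nuclei, the SNc-VTA libraries were higher in dopamine neuron, midbrain and myelin genes, and the olfactory bulb libraries in forebrain interneuron, mitral and tufted, and immediate early genes. Of 19329 genes tested, 11450 differed between the regions, 6096 higher and 5354 lower in SNc-VTA. The largest rises that met the fixed naming rule included Dlk1, a Notch ligand-like protein of midbrain neurons (7.64 ± 0.13; 94.7 ± 4.89 against 0.408 ± 0.0931 CPM), Syt2, a fast calcium sensor of transmitter release (5.42 ± 0.11), the serotonin receptor gene Htr2c (5.14 ± 0.21) and the glycine receptor gene Glra3 (4.26 ± 0.10). The largest falls included the odorant receptor gene Olfr111 (-8.42 ± 0.18), the potassium channel gene Kcnh3 (-7.64 ± 0.13), Frmd7 (-7.24 ± 0.16) and Cdhr1, a cadherin of mitral and tufted cells (-6.77 ± 0.15; 1.59 ± 0.614 against 146 ± 15.5 CPM). Each of these genes moved the same way in all 3 mice (adjusted p of at most 2.82e-07). These sums carry the classes' different shares, such as 27.9% neuron-like nuclei against 89.6%.

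Among dopamine neuron genes, 14 of 16 measured members were higher in SNc-VTA, 1 lower and 1 did not pass (adjusted over the list alone, 14 higher and 1 lower). Slc6a3, the dopamine transporter (4.67 ± 0.22; 145 ± 31.4 against 4.94 ± 1.55 CPM), Ddc, which makes dopamine from its precursor (4.58 ± 0.16), Slc18a2, the vesicular monoamine transporter (3.38 ± 0.13), and Drd2, the dopamine autoreceptor (4.19 ± 0.16), were all higher (adjusted p of at most 6.83e-07). Th, the rate-limiting enzyme of dopamine synthesis, which dopaminergic interneurons of the olfactory bulb also make, stood at 55.2 ± 16.0 against 45.7 ± 4.36 CPM and did not pass (log2 0.02 ± 0.18, adjusted p = 0.926). Nr4a2, a factor of dopamine neuron identity that other neurons also make, was lower (-0.61 ± 0.17, adjusted p = 0.0151). The list ranked above other genes (camera adjusted p = 2.48e-07, and adjusted p = 0.384 with an estimated correlation). All 14 midbrain patterning transcription factors were higher in SNc-VTA (adjusted over the list alone, 14). En1, needed for midbrain dopamine neurons, was at least 485-fold higher, with no UMI in the olfactory bulb. Sox14, a factor of midbrain GABA neurons, was at least 114-fold higher, and Gata3 was 353-fold (95% counting interval 97.4 to 2916) higher (camera adjusted p = 1.20e-06, and adjusted p = 0.295 with an estimated correlation).

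Forebrain genes went the other way. All 14 forebrain and olfactory bulb interneuron transcription factors were lower in SNc-VTA (adjusted over the list alone, 14; camera adjusted p = 6.14e-10, and adjusted p = 0.295 with an estimated correlation). Foxg1, the telencephalon's master factor (-8.78 ± 0.20), Meis2, of olfactory bulb granule cells (-5.39 ± 0.14; 73.1 ± 12.5 against 2623 ± 147 CPM), Dlx1, of forebrain GABA neurons (-5.39 ± 0.22), and Sp8 (-5.69 ± 0.21) were among them (adjusted p of at most 3.00e-07). Of the mitral and tufted neuron genes, 1 of 10 measured members were higher in SNc-VTA, 9 lower and 0 did not pass (adjusted over the list alone, 1 higher and 9 lower; camera adjusted p = 7.01e-05, and adjusted p = 0.295 with an estimated correlation). Eomes (-8.79 ± 0.22), the vesicular glutamate transporter gene Slc17a7 (-6.56 ± 0.28) and Reln (-3.64 ± 0.10) were lower, and Lhx5, which midbrain neurons also make, was the higher one (3.24 ± 0.33). Of the neurogenesis and immature neuron genes, 0 of 12 measured members were higher in SNc-VTA, 7 lower and 5 did not pass (adjusted over the list alone, 0 higher and 7 lower; camera adjusted p = 0.00784, and adjusted p = 0.306 with an estimated correlation). Dcx, a microtubule protein of migrating neuroblasts (-2.62 ± 0.09), Igfbpl1 (-6.42 ± 0.17) and Sox4 (-2.47 ± 0.12) were lower, whereas Sox11 (-0.03 ± 0.14) and Tubb3 (-0.21 ± 0.12) did not pass. All 10 immediate early genes, which neuronal activity and handling both raise, were lower in SNc-VTA (adjusted over the list alone, 10; camera adjusted p = 1.20e-06, and adjusted p = 0.295 with an estimated correlation). Fosb (-4.92 ± 0.20), Npas4 (-3.70 ± 0.10), Fos (-2.47 ± 0.10) and Arc (-2.41 ± 0.09) were examples (adjusted p of at most 3.17e-07). Of the glutamate transmission genes, 2 of 10 measured members were higher in SNc-VTA, 8 lower and 0 did not pass (adjusted over the list alone, 2 higher and 8 lower; camera adjusted p = 0.00195, and adjusted p = 0.384 with an estimated correlation). Gria2, an AMPA receptor subunit (-1.44 ± 0.09), was lower, and Slc17a6, the vesicular glutamate transporter of the midbrain (2.10 ± 0.11), was higher. Of the olfactory ensheathing cell genes, 1 of 7 measured members were higher in SNc-VTA, 6 lower and 0 did not pass (adjusted over the list alone, 1 higher and 6 lower; camera adjusted p = 0.00281, and adjusted p = 0.295 with an estimated correlation), with Npy (-4.56 ± 0.15) and Frzb (-4.56 ± 0.11) lower.

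Myelin genes, non-telencephalic astrocyte genes and most microglia genes were higher in SNc-VTA, as were 12 of 19 Parkinson's disease genes. All 14 myelin genes were higher (adjusted over the list alone, 14; camera adjusted p = 5.04e-10, and adjusted p = 0.295 with an estimated correlation), with Mbp at 1958 ± 120.5 against 175 ± 46.5 CPM (3.30 ± 0.13), Plp1 at 3211 ± 397 against 243 ± 73.5 CPM (3.55 ± 0.15) and Mog at 3.78 ± 0.13, beside an oligodendrocyte-like share of 34.3% against 2.03%. All 8 non-telencephalic astrocyte genes were higher (adjusted over the list alone, 8; camera adjusted p = 1.07e-04, and adjusted p = 0.295 with an estimated correlation), such as Agt, the angiotensin precursor (2.40 ± 0.19), and Itih3 (3.68 ± 0.13). Within neuron-like nuclei 7 of the 8 were also higher, and Irx2, Irx3 and Irx5 are midbrain patterning factors as well, so this rise is not of astrocytes alone. Of the microglia genes, 9 of 10 measured members were higher in SNc-VTA, 0 lower and 1 did not pass (adjusted over the list alone, 10 higher and 0 lower; camera adjusted p = 0.00144, and adjusted p = 0.448 with an estimated correlation). Tmem119 (1.43 ± 0.14), Csf1r (0.94 ± 0.13) and P2ry12 (0.80 ± 0.11) were higher. Of the Parkinson's disease genes, 12 of 19 measured members were higher in SNc-VTA, 1 lower and 6 did not pass (adjusted over the list alone, 12 higher and 1 lower; camera adjusted p = 0.00794, and adjusted p = 0.295 with an estimated correlation). Uchl1, a neuronal ubiquitin hydrolase (1.99 ± 0.10; 73.7 ± 8.24 against 16.1 ± 2.33 CPM), Fbxo7, a ubiquitin ligase subunit (1.29 ± 0.11), Mapt, which encodes tau (1.27 ± 0.09), and Prkn, which encodes parkin (0.87 ± 0.08), were higher (adjusted p of at most 2.43e-05). The lower member was SNCA itself, described below. Camera with a preset correlation called 12 of 26 lists, 6 up and 6 down, and 0 with an estimated one. The estimated form has few residual degrees of freedom here, so it could hardly call any list and decides little. The midbrain patterning factors, with an estimated correlation of -0.0243, did not pass it either. Fry, which asks only whether a list moves on balance one way, called 21.

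**Figure D2:**
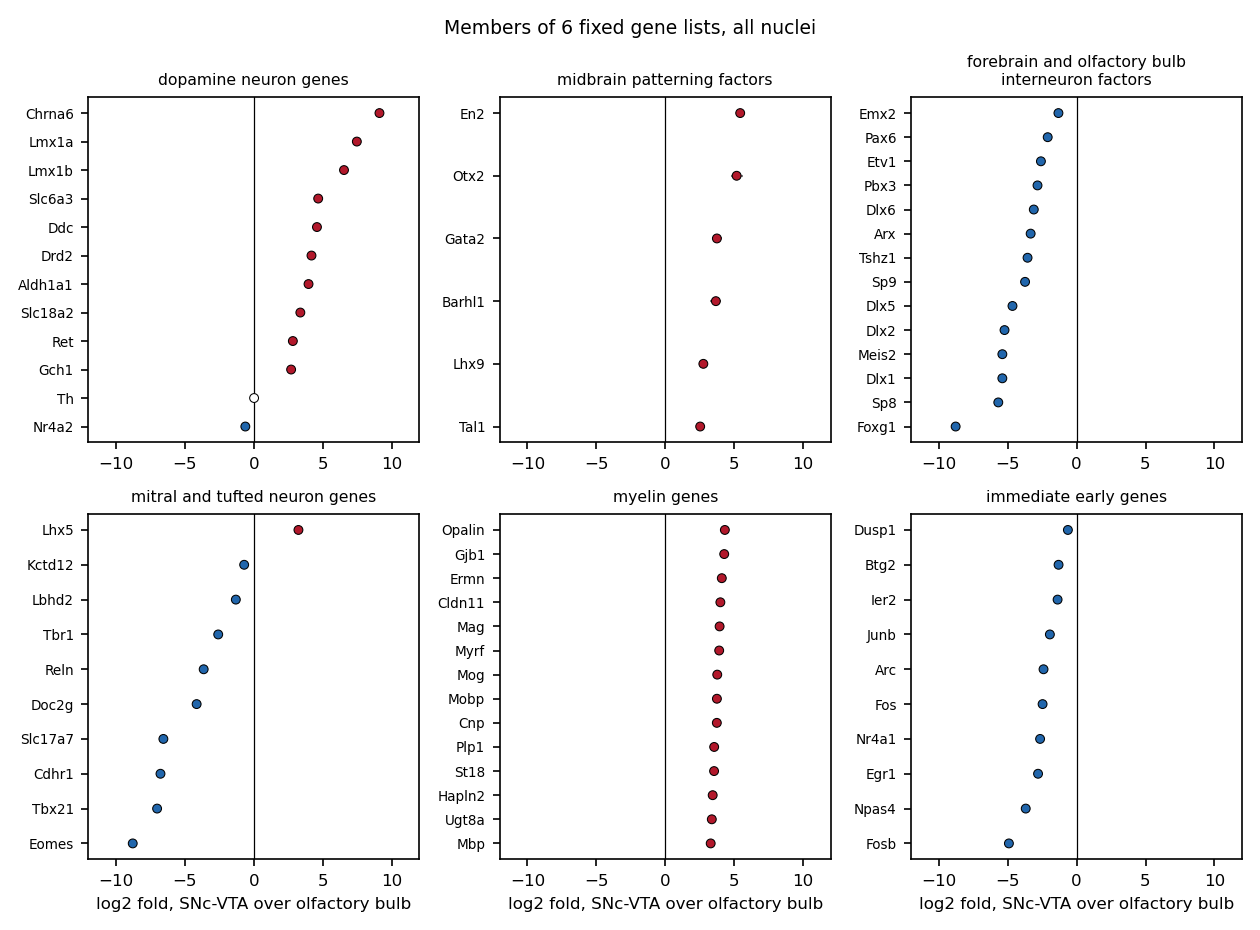
Difference between regions (log2 fold, SNc-VTA over olfactory bulb, horizontal axis) of the members of 6 fixed lists over all nuclei, with error bars of 1 SE and filled points where the adjusted p passed. Myelin and midbrain genes lie to the right and forebrain and immediate early genes to the left, and genes with 3 or fewer UMIs in a region are left out.

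Within neuron-like nuclei, SNc-VTA was higher in midbrain and dopamine neuron genes, and the olfactory bulb in forebrain interneuron factors and immediate early genes. Of 18215 genes tested, 10979 differed, 5740 higher and 5239 lower in SNc-VTA. The regions hold different neurons: dopaminergic-like, GABAergic-like and glutamatergic-like clusters in SNc-VTA, and granule-like, periglomerular-like, mitral/tufted-like and neuroblast-like clusters in the olfactory bulb. Dlk1 (8.21 ± 0.14; 122 ± 16.0 against 0.353 ± 0.128 CPM), Htr2c (7.01 ± 0.13), the transcription factor genes Zfhx3 (6.97 ± 0.19), Bnc2 (6.71 ± 0.28) and Tcf7l2, a factor of thalamic and midbrain glutamate neurons (6.08 ± 0.19), and Syt2 (5.91 ± 0.12) were among the largest rises. Shisa8, an AMPA receptor partner (-8.27 ± 0.14; 0.429 ± 0.158 against 113 ± 16.9 CPM), Frmd7 (-7.73 ± 0.20), Lgr6, an R-spondin receptor (-7.61 ± 0.11), and Kcnh3 (-7.01 ± 0.13) were among the largest falls. Olfr111 was 1770.5-fold (95% counting interval 606 to 8588) lower, with 3 UMIs in SNc-VTA neuron-like nuclei. These 11 genes moved the same way in all 3 mice (adjusted p of at most 2.55e-07).

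Of the dopamine neuron genes in neuron-like nuclei, 14 of 16 measured members were higher in SNc-VTA, 0 lower and 2 did not pass (adjusted over the list alone, 14 higher and 0 lower). Ddc (5.36 ± 0.17), Drd2 (4.79 ± 0.16), Lmx1b, a factor of dopamine neuron development (7.75 ± 0.19), and the nicotinic receptor gene Chrna6 (9.47 ± 0.26) were higher, and En1 was at least 712-fold higher. Th stood at 79.5 ± 26.3 against 48.5 ± 5.28 CPM and did not pass (log2 0.46 ± 0.21, adjusted p = 0.0858). All 14 midbrain patterning factors were higher and all 14 forebrain interneuron factors lower (adjusted over the lists alone, 14 and 14), with Foxg1 at -9.34 ± 0.25, Meis2 at -4.96 ± 0.12 and Pbx3, also of granule cells, at -2.58 ± 0.11. All 10 immediate early genes were lower (adjusted over the list alone, 10), such as Fosb (-4.47 ± 0.18), Arc (-3.91 ± 0.14), Npas4 (-3.05 ± 0.11) and Egr1 (-2.59 ± 0.14). Of the GABA transmission genes, 3 of 9 measured members were higher in SNc-VTA, 6 lower and 0 did not pass (adjusted over the list alone, 3 higher and 6 lower). Gad1, which makes GABA (-2.91 ± 0.08), and Slc32a1, its vesicular transporter (-1.18 ± 0.17), were lower, and the GABA-B receptor gene Gabbr2 (1.65 ± 0.08) was higher. Of the synuclein and synaptic vesicle genes, 5 of 13 measured members were higher in SNc-VTA, 6 lower and 2 did not pass (adjusted over the list alone, 5 higher and 6 lower). Sncb, beta-synuclein (0.99 ± 0.11), and Cplx2 (1.00 ± 0.08) were higher, Sncg, gamma-synuclein, was at least 147-fold higher, and Snap25 (-1.13 ± 0.07) and Syn2 (-1.34 ± 0.08) were lower.

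Of the Parkinson's disease genes in neuron-like nuclei, 10 of 19 measured members were higher in SNc-VTA, 1 lower and 8 did not pass (adjusted over the list alone, 10 higher and 1 lower). Uchl1 (2.49 ± 0.12), Sncaip, which encodes a synuclein partner (1.72 ± 0.10), Prkn (1.04 ± 0.08) and Lrrk2, a kinase (0.96 ± 0.11), were higher (adjusted p of at most 1.15e-04). Pink1 (0.09 ± 0.10), Vps35 (0.07 ± 0.07) and Gba (0.08 ± 0.11) did not pass. Of the pacemaking and calcium channel genes, 4 of 11 measured members were higher in SNc-VTA, 4 lower and 3 did not pass (adjusted over the list alone, 4 higher and 4 lower). Kcnn3, a calcium-activated potassium channel that shapes dopamine neuron firing (2.07 ± 0.12; 147 ± 33.0 against 29.9 ± 3.37 CPM), and Scn1a (0.89 ± 0.08) were higher, and the L-type calcium channel genes Cacna1c (-1.58 ± 0.09) and Cacna1d (-1.41 ± 0.07) were lower. The mitochondrially encoded genes counted 1 higher, 6 lower and 4 not passing (adjusted over the list alone 1 and 6), with mt-Nd3 at -1.03 ± 0.09 and mt-Cytb at -0.67 ± 0.10. The myelin genes, which neurons are not known to make counted 13 higher, 0 lower and 1 not passing (adjusted over the list alone 13 and 0), with Plp1 at 291 ± 147 against 63.7 ± 26.3 CPM. No level of free RNA was computed for neuron-like nuclei, which make up most of the olfactory bulb's RNA.

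In astrocyte-like nuclei, most non-telencephalic astrocyte genes were higher and most telencephalic astrocyte genes lower in SNc-VTA. Of 9856 genes tested, 1665 differed, 704 higher and 961 lower in SNc-VTA. Agt (5.19 ± 0.29; 529.8 ± 117 against 15.8 ± 6.44 CPM) and Aldh1a1, a retinoic acid-making enzyme (3.89 ± 0.21; 924 ± 82.6 against 63.4 ± 7.84 CPM), were higher. The Iroquois factor genes Irx2 and Irx5 were each at least 10.9-fold higher, with no UMI in the olfactory bulb. Lyn, a Src-family kinase (-6.95 ± 0.24; 4.46 ± 1.74 against 578 ± 25.4 CPM), Fam184b (-7.31 ± 0.38), Ano1, a chloride channel (-6.78 ± 0.38), the sialyltransferase gene St6galnac5 (-5.61 ± 0.21) and the heparan sulfate enzyme gene Hs3st3a1 (-5.09 ± 0.21) were lower. Foxg1 was at least 206-fold lower and Lhx2 at least 85.6-fold lower, with no UMI in SNc-VTA astrocyte-like nuclei. Chrdl1, a BMP antagonist, was 261-fold (95% counting interval 87.3 to 1282) lower. Of the non-telencephalic astrocyte genes, 5 of 7 measured members were higher in SNc-VTA, 0 lower and 2 did not pass (adjusted over the list alone, 5 higher and 0 lower), among them Itih3 (1.78 ± 0.19) and Sparc (1.96 ± 0.21). Of the telencephalic ones, 1 of 7 measured members were higher in SNc-VTA, 5 lower and 1 did not pass (adjusted over the list alone, 1 higher and 5 lower), with Mfge8 (-1.73 ± 0.17) and Pax6 (-2.44 ± 0.27) lower and Gli3 (0.68 ± 0.17) higher. The genes named so far moved the same way in all 3 mice (adjusted p of at most 0.00194).

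Among general astrocyte genes, 2 of 8 measured members were higher in SNc-VTA, 2 lower and 4 did not pass (adjusted over the list alone, 3 higher and 2 lower). Gfap, an intermediate filament (-2.45 ± 0.24; 32.2 ± 16.0 against 176 ± 61.5 CPM), and Slc1a3, a glutamate transporter (-2.01 ± 0.16), were lower, and Ntsr2 (0.59 ± 0.15) and Slc4a4 (0.41 ± 0.15) were higher, the last not without the mouse block (adjusted p = 0.0999). The mitochondrially encoded genes counted 0 higher, 9 lower and 2 not passing (adjusted over the list alone 0 and 10), and the cytoplasmic ribosomal protein genes 0 higher, 8 lower and 6 not passing (adjusted over the list alone 0 and 8), with mt-Co3 at -1.26 ± 0.17 and Rps19 at -1.44 ± 0.32. The glutamate transmission genes counted 0 higher, 6 lower and 3 not passing (adjusted over the list alone 0 and 6), and 1 of the called ones lay above 2 times the free-RNA level. Among them the AMPA receptor gene Gria2 was lower (-1.75 ± 0.15). Apoe (-1.06 ± 0.15) and Fabp7 (-2.79 ± 0.21) were also lower. The myelin genes counted 9 higher, 0 lower and 2 not passing (adjusted over the list alone 11 and 0), with Plp1 at 1014 ± 447 against 179 ± 33.3 CPM, and 0 of the called myelin genes lay above 2 times the level that free RNA would give. Granule cell genes such as Meis2 (-2.78 ± 0.17, 0.917 times the free-RNA level) were lower beside them. The class is held by different clusters in each region: of the 1998 nuclei of the largest astrocyte-like cluster, 0, 1 and 2 came from the 3 olfactory bulb libraries. The authors named more olfactory bulb astrocytes in M9377 and M9378, 231 and 209 against 87 and 99 here, so that side may be only a part of them. Without M9377 the fit called 1095 genes, and on simulated data 41.7% of genes changed 2-fold were called. The simulation did not vary depth, so it does not part depth from the number of libraries and their spread.

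In oligodendrocyte-like nuclei, fewer genes differed than in astrocyte-like ones, and most myelin genes did not pass. Of 12116 genes tested, 373 differed, 190 higher and 183 lower in SNc-VTA. Fth1, the ferritin heavy chain that stores iron (1.58 ± 0.13; 1633 ± 226 against 537 ± 27.3 CPM), Resp18, an endocrine granule protein (3.36 ± 0.41), Arhgap15 (2.42 ± 0.41), Rhoj, a Rho-family GTPase (1.72 ± 0.34), and Ttc12 (1.66 ± 0.33) were higher. The calcium channel subunit gene Cacna2d1 (-2.24 ± 0.17; 38.3 ± 12.3 against 183 ± 60.1 CPM), Zfhx4, a transcription factor (-1.45 ± 0.17), Piezo2, a mechanosensitive channel (-1.39 ± 0.21), and Agmo, an ether lipid enzyme (-1.20 ± 0.15), were lower. These 9 genes moved the same way in all 3 mice (adjusted p of at most 5.86e-04). Of the myelin genes, 2 of 14 measured members were higher in SNc-VTA, 1 lower and 11 did not pass (adjusted over the list alone, 4 higher and 2 lower). Cnp (0.79 ± 0.14) and the connexin gene Gjb1 (0.74 ± 0.17) were higher, and Hapln2, a matrix protein of nodes of Ranvier, was lower (-0.49 ± 0.13). The cytoplasmic ribosomal protein genes counted 3 higher, 0 lower and 11 not passing (adjusted over the list alone 8 and 0), such as Rps8 (0.78 ± 0.18). The mitochondrially encoded genes counted 0 higher, 3 lower and 8 not passing (adjusted over the list alone 0 and 7), such as mt-Co2 (-0.43 ± 0.12). Apoe, a lipid carrier, was lower (-0.75 ± 0.15), and Foxj1, a ciliary factor, was higher (2.67 ± 0.56). Neuronal genes near the free-RNA level moved with the regions' neurons, such as Slc6a3 (at least 12.8-fold higher, 1.46 times that level) and Meis2 (-1.96 ± 0.20, 0.559 times). Of the genes named here, Fth1, Cacna2d1, Zfhx4 and Meis2 passed without the mouse block and the other 14 did not (adjusted p of 0.0740 to 0.341). Without the mouse block the fit called 35 genes, without M9377 164 and without M9378 236.

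In oligodendrocyte precursor-like nuclei, 273 of 6725 genes differed, 112 higher and 161 lower in SNc-VTA. Chl1, a neural adhesion molecule, was lower (-3.36 ± 0.19; 53.5 ± 3.44 against 545 ± 31.8 CPM), as were the zinc finger gene Zfp804b (-4.87 ± 0.30), the tetraspanin gene Cd9 (-0.96 ± 0.17) and Apoe (-0.70 ± 0.15). The collagen genes Col9a1 and Col27a1 were at least 8.62-fold higher and 35.8-fold (95% counting interval 6.34 to 1419.8) higher, Irx2 was 10.6-fold (95% counting interval 2.85 to 88.4) higher and Foxg1 was at least 27.0-fold lower. These 8 genes moved the same way in all 3 mice (adjusted p of at most 0.00104). Of the precursor genes themselves, 1 of 8 measured members were higher in SNc-VTA, 0 lower and 7 did not pass (adjusted over the list alone, 1 higher and 0 lower), the higher one being Pcdh15, a protocadherin (0.40 ± 0.09). Of the glutamate transmission genes, 1 of 6 measured members were higher in SNc-VTA, 5 lower and 0 did not pass (adjusted over the list alone, 1 higher and 5 lower), with Grm5 (0.53 ± 0.11) higher and Gria1 (-1.28 ± 0.20) and Grin2a (-2.25 ± 0.38) lower, the last at 0.434 times the free-RNA level. Of these 6 called genes, 2 lay above 2 times that level. Sparc (2.26 ± 0.45) and Aldh1a1 (2.26 ± 0.51) were higher, as in the astrocyte-like nuclei. The non-telencephalic astrocyte genes, which include Sparc, counted 2 higher, 0 lower and 2 not passing (adjusted over the list alone 2 and 0). The myelin genes counted 7 higher, 0 lower and 1 not passing (adjusted over the list alone 7 and 0), with Plp1 at 700.3 ± 386 against 117 ± 44.0 CPM (2.55 ± 0.19), and 0 of the called ones lay above 2 times the free-RNA level. Without the mouse block Pcdh15 and Grm5 did not pass (adjusted p = 0.0953 and 0.0648). The DESeq2 test called 88 genes.

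In microglia-like nuclei, Apoe and the macrophage genes Mrc1, F13a1 and Lyz2 were lower in SNc-VTA, and 9 of 10 microglia genes did not pass. Of 5396 genes tested, 250 differed, 109 higher and 141 lower. Apoe, a lipid carrier, was lower (-3.19 ± 0.13; 269.7 ± 47.7 against 2454 ± 507 CPM). The granule neuron genes Meis2 (-5.08 ± 0.58) and Synpr (-3.89 ± 0.42) were lower still, at 0.313 and 0.999 times the free-RNA level. Mrc1, the mannose receptor of border-associated macrophages (-2.73 ± 0.28; 40.3 ± 30.7 against 289.9 ± 139.8 CPM), F13a1, a clotting factor subunit of macrophages (-2.36 ± 0.30), and Lyz2, a macrophage lysozyme (-2.51 ± 0.28), were also lower, as was Tyrobp, an immune signalling adaptor (-0.71 ± 0.18). No cluster was named border-associated macrophages, so such cells may lie within this class. Whether these falls come from microglia or from the share of macrophages in the class was not tested. Of the microglia genes, 1 of 10 measured members were higher in SNc-VTA, 0 lower and 9 did not pass (adjusted over the list alone, 1 higher and 0 lower), the higher one being Tmem119 (0.70 ± 0.14; 859.7 ± 186 against 513 ± 30.3 CPM). Of the microglial activation genes, 0 of 5 measured members were higher in SNc-VTA, 2 lower and 3 did not pass (adjusted over the list alone, 0 higher and 2 lower). The 8 genes named here moved the same way in all 3 mice (adjusted p of at most 0.00991). All 11 mitochondrially encoded genes were lower (adjusted over the list alone, 11), from mt-Nd5 (-0.61 ± 0.18) to mt-Nd3 (-2.37 ± 0.30). Their level is a sign of cytoplasm carried with a nucleus. All 6 measured myelin genes were higher (adjusted over the list alone, 6), such as Plp1 at 1366 ± 763 against 157 ± 128 CPM (2.36 times the free-RNA level) and Mbp (2.21 ± 0.25, 0.714 times). Of these 6 myelin genes, 3 lay above 2 times that level. Without the mouse block Tyrobp and mt-Nd5 did not pass (adjusted p = 0.0588 and 0.170), and the fit called 122 genes, without M9376 102 and without M9377 142. The DESeq2 test called 81, and the counts with at least 1000 genes per nucleus and with doublets kept were 92 and 414.

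The difference between regions itself differed between astrocyte-like and oligodendrocyte-like nuclei at 614 of 11071 genes, 171 with a higher and 443 with a lower value in astrocyte-like nuclei. Of these, 531 were also called within astrocyte-like nuclei, 387 had estimates of opposite sign in the 2 classes, and 377 lay above 2 times the free-RNA level in astrocyte-like nuclei. The 387 count signs whether or not each estimate passed, and only 373 genes in all passed in oligodendrocyte-like nuclei. Reln, a secreted guidance protein, went opposite ways (0.87 in astrocyte-like and -3.59 in oligodendrocyte-like nuclei; difference 4.30 ± 0.36). So did Syn2, a synapsin (1.23 in astrocyte-like and -1.14 in oligodendrocyte-like nuclei; difference 2.38 ± 0.37), and Csmd1, a complement regulator (-3.36 in astrocyte-like and 1.54 in oligodendrocyte-like nuclei; difference -4.69 ± 0.39). The same held for Cd9, a tetraspanin (-1.40 in astrocyte-like and 0.66 in oligodendrocyte-like nuclei, difference -2.10 ± 0.30), and Rps8 (-0.95 in astrocyte-like and 0.78 in oligodendrocyte-like nuclei, difference -1.71 ± 0.27). These 5 genes passed in both classes, but Syn2, Cd9 and Rps8 did not pass in oligodendrocyte-like nuclei without the mouse block (adjusted p = 0.234, 0.261 and 0.0740). In oligodendrocyte-like nuclei 0 of the called synuclein and synaptic vesicle genes, Syn2 among them, lay above 2 times the free-RNA level. Dock5, a Rac activator of myelinating cells, had a difference of 4.75 ± 0.47 (4.47 in astrocyte-like and -0.22 in oligodendrocyte-like nuclei), and Nrg1, a growth factor for glia, of -4.40 ± 0.25 (-3.99 in astrocyte-like and 0.48 in oligodendrocyte-like nuclei), although in astrocyte-like nuclei Nrg1 lay at 1.88 times the free-RNA level, under the bound of 2. The differences of Lypd6 (-4.72 ± 0.41), the ephrin gene Efna5 (-5.48 ± 0.41) and Lyn (-6.26 ± 0.64) stood beside falls in SNc-VTA in astrocyte-like nuclei, of -4.74, -4.64 and -6.95. In oligodendrocyte-like nuclei Lypd6 and Efna5 did not pass (adjusted p = 0.886 and 0.615), and Lyn was too low to test. Myelin genes such as Plp1 (2.33 ± 0.37) and Mag (3.11 ± 0.54) were among the 614 from their rise in astrocyte-like nuclei at 1.16 and 0.741 times the free-RNA level. The genes named here had adjusted p of at most 7.04e-04. Without the library block the fit called 393 genes, without M9377 259 and without M9378 345.

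SNCA transcripts were lower in SNc-VTA than in the olfactory bulb, and among the neuron-like nuclei of SNc-VTA they were highest in dopaminergic-like ones. The level is the sum of the SNCA-GR and mouse Snca features, because the feature table of the SNc-VTA library of M9377 lists no SNCA-GR. In that library 1055 UMIs were counted as Snca against 12 to 34 in the other libraries. Over all nuclei it was 17.7 ± 3.23 CPM in SNc-VTA and 30.4 ± 1.37 CPM in the olfactory bulb (n = 3 each; log2 -1.01 ± 0.12, edgeR adjusted p = 1.28e-04), lower in all 3 mice. The exact permutation p was 0.1, two-sided, the smallest possible. The CPM are scaled by UMI totals and the log2 difference by TMM, so the ratio of these means is smaller than the log2 value gives. Within neuron-like nuclei it was 14.6 ± 2.11 against 31.2 ± 1.45 CPM (log2 -1.31 ± 0.11, adjusted p = 1.54e-05). In oligodendrocyte-like nuclei it was 27.7 ± 12.1 against 40.6 ± 8.97 CPM and did not pass (log2 -0.66 ± 0.27, adjusted p = 0.235). Astrocyte-like, precursor-like and microglia-like nuclei held 35, 32 and 3 SNCA UMIs in SNc-VTA and 7, 10 and 0 in the olfactory bulb, too few to test at this depth.

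In SNc-VTA, dopaminergic-like neurons held 42.0 ± 11.2 against 9.37 ± 1.49 CPM (log2 2.27 ± 0.11, adjusted p = 3.40e-10) in other neuron-like nuclei, in 3 of 3 libraries. Oligodendrocyte-like nuclei, more numerous, held 825 of the 2485 SNCA UMIs of SNc-VTA and dopaminergic-like neurons 505. By library, their levels were 17.3 against 31.6 CPM in M9376, 41 against 40.4 CPM in M9377 and 24.9 against 53.8 CPM in M9378. GABAergic-like and glutamatergic-like neurons there held 9.53 ± 1.56 and 9.94 ± 1.67 CPM. In the olfactory bulb, mitral/tufted-like neurons, the output neurons, held 37.7 ± 0.514 against 30.1 ± 1.61 CPM (log2 0.27 ± 0.08, adjusted p = 0.00867) in other neuron-like nuclei, in 3 of 3 libraries. Granule-like, periglomerular-like and neuroblast-like neurons there held 33.5 ± 1.48, 21.1 ± 2.67 and 10.2 ± 2.15 CPM. Neuron-like nuclei of no named kind there held 49.9 ± 8.92 CPM, above the mitral/tufted-like neurons in all 3 libraries. Neuron-like nuclei of SNc-VTA were below the pooled non-neuronal classes, at 14.6 ± 2.11 against 22.2 ± 9.20 CPM (log2 -0.64 ± 0.16, adjusted p = 0.0144) and in 3 of 3 libraries. Oligodendrocyte-like nuclei held 825 of the 919 UMIs of that pool, and 5 other classes had lower means than the neurons, 7.25 ± 2.55 CPM in astrocyte-like, 13.2 ± 2.90 in precursor-like, 8.57 ± 6.04 in committed precursor-like, 1.88 ± 2.20 in microglia-like and 5.36 ± 4.83 in endothelial-like nuclei. The 81 pericyte-like nuclei held 1 UMI in M9376 and 2 in M9377, which come to 17.05 and 51.63 CPM, above the neurons there, and the 40 fibroblast-like nuclei held none. Neuron-like nuclei of the olfactory bulb were above the pooled classes there, at 31.2 ± 1.45 against 18.7 ± 5.31 CPM (log2 1.00 ± 0.18, adjusted p = 7.96e-04) and in 3 of 3 libraries. The exact permutation p, two-sided, was 0.1 for each contrast, the smallest possible, except 0.3 for neurons against the non-neuronal classes of SNc-VTA. The mitral/tufted difference passed with the mouse as a block and not without it (0.27), nor without M9376 (0.24). The difference from the non-neuronal classes of SNc-VTA did not pass without M9377 (-0.41). The difference between neuron-like nuclei and the non-neuronal classes of the olfactory bulb did not pass on UMI sums thinned to 1 depth (0.15), nor the mitral/tufted one in DESeq2 (0.24) or on thinned sums (0.34).

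**Figure D3:**
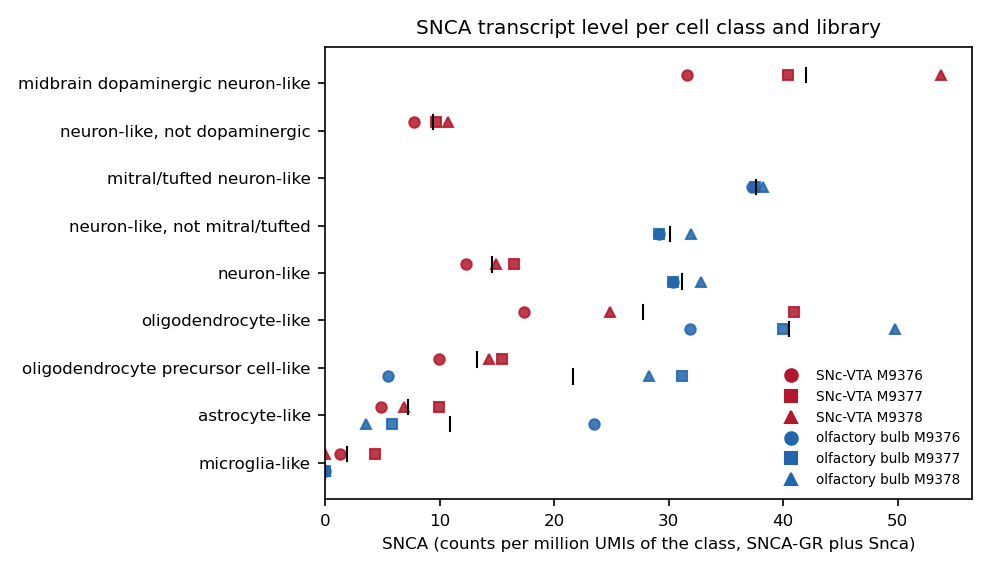
SNCA level (CPM of the class, SNCA-GR plus Snca, horizontal axis) per cell class, with 1 point per library (colour for the region, shape for the mouse) and a bar at the mean. Dopaminergic-like neurons average 42.0 CPM in SNc-VTA and other neuron-like nuclei there 9.37 CPM.

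Long reads showed a larger share of SNCA transcripts with a disrupted iron-response element in SNc-VTA than in the olfactory bulb. This element is a stem-loop of the 5' untranslated region through which iron-regulatory proteins hold back translation, and the deposited table counts reads over splice junctions that disrupt it (dIRE1 to dIRE7) or keep it (IRE). The dIRE share of assigned reads was 22.0% ± 0.447 in SNc-VTA and 18.1% ± 0.117 in the olfactory bulb (n = 2 each), higher by 4.25 percentage points in M9377 and 3.45 in M9378. Within mice, Fisher's exact test, two-sided and adjusted over 18 tests, gave p = 5.26e-04 and 0.00665. The most abundant of them, dIRE1, followed, at 17.5% ± 0.283 in SNc-VTA and 13.8% ± 0.329 in the olfactory bulb (adjusted Fisher's exact p = 6.35e-04 and 0.00181). The rarer dIRE2 was lower, at 0.474% ± 0.131 in SNc-VTA and 1.56% ± 0.319 in the olfactory bulb (adjusted Fisher's exact p = 2.49e-05 and 0.0164). For dIRE3 the shares were 0.835% and 0.316%, and Fisher's exact test passed in M9377 alone (adjusted p = 0.00883 and 0.0737), while dIRE4 stood at 2.26% and 2.21% and passed in neither mouse. Over the 4 libraries an exact permutation test, two-sided, of dIRE, dIRE1 and dIRE2 gave p = 0.333 and a sign-flip within mice p = 0.5, each the smallest that 2 mice allow. Assigned reads per nucleus came to 0.285 and 0.286 in SNc-VTA and 0.574 and 0.486 in the olfactory bulb. The regions hold different cell types, and how far this makes the dIRE difference was not tested. In the authors' oligodendrocytes the dIRE share was 20.7% in SNc-VTA against 17.5% in M9377, and 20.02% against 20.48% in M9378. In their astrocytes it was 57.1% against 25.5% and 54.2% against 19.5%, on few reads in SNc-VTA. Types named dopamine neurons stood at 23.8% against 21.7% and 30.7% against 22.1%. Fisher's test and the intervals take reads as independent molecules, and whether the authors collapsed reads by UMI is not stated, so they cover counting error only. The assigned total was 1.08 to 1.19 times the separate SNCA read count, although the deposited description calls the second a superset of the first. The assigned total is the denominator here.

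**Figure D4:**
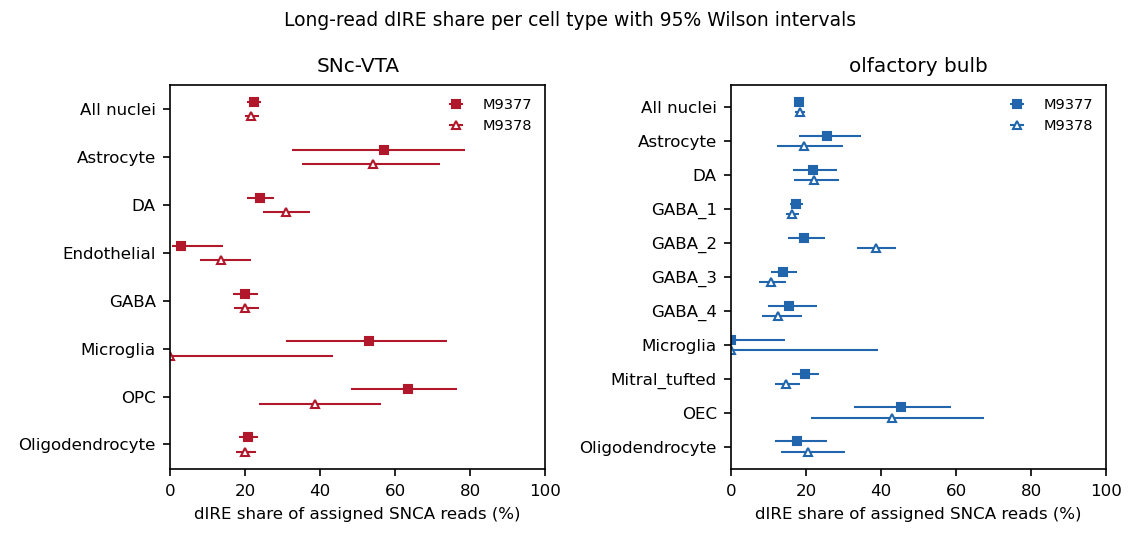
dIRE share of assigned SNCA long reads (percent, horizontal axis) in all nuclei and in the cell types named by the authors, in 1 panel per region, with 1 point per mouse and 95% Wilson intervals. The all-nuclei shares average 22.0% in SNc-VTA and 18.1% in the olfactory bulb, and wide intervals mark cell types with few reads.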

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

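The own-cluster tests of the SNc-VTA library of M9376, the free-RNA test against the spread of its genes, and for SNCA the tests of the share of neurons and of the missing feature, were chosen after seeing the result, whereas the other tests in this part were chosen before. The difference between regions differed between astrocyte-like and oligodendrocyte-like nuclei at 614 genes, by a test of the difference itself. SNCA stood lower in neuron-like nuclei than in the pooled non-neuronal classes of SNc-VTA (log2 -0.6442) and higher in the olfactory bulb (1.0017), with all 3 libraries of each region on its side, and this difference between regions was not tested. In SNc-VTA the pool is set by oligodendrocyte-like nuclei, at 27.7 CPM against 14.6 in neurons, while 5 other non-neuronal classes had lower means than the neurons, 1.88 to 13.2 CPM, and pericyte-like and fibroblast-like nuclei held 3 and 0 UMIs. Of the nuclei of the SNc-VTA library of M9376, 11317 sat in clusters found almost wholly in that library. They carry no class name, so the comparisons within classes left them out, while the sums over all nuclei and the denominator of the class shares include them.

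The region differences within glial classes were weighed against free RNA from the neurons and glia of each region. The test chosen before held that free RNA would leave at least 90% of the called genes at or below 2 times its level, and 75.5% lay above in astrocyte-like, 67.56% in oligodendrocyte-like, 63.74% in precursor-like and 73.6% in microglia-like nuclei. It decides nothing, since 20% to 32.61% of the free-RNA genes themselves lay above that bound. Above the 90th percentile of those genes lay 61.14%, 55.23%, 35.16% and 62% of the called genes in these 4 classes, and 49.6%, 48.46%, 26.56% and 52.26% of those at 20 CPM or more in all nuclei, where the bounds were at most 10% if free RNA made them and over 50% if not. Free RNA as the source of the calls and differences within the classes cannot be told apart on these values, because at 20 CPM or more every share lay above 10% and none above 50% by more than its Wilson 95% interval.

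Of 10 splits of the libraries only 4 part all 3 mice, too few for a share under 0.05. The real one gave 11450 genes over all nuclei, 10979 in neurons, 1665 in astrocytes, 373 in oligodendrocytes, 273 in precursors, 250 in microglia and 614 for the interaction, and the highest other gave 0 for each, so 1 of 4 was as large. For the gene lists the real split gave 12 and the highest other 12, so 2 of 4 were as large, and a split parting 1 mouse gave 14.

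The lower SNCA in SNc-VTA was weighed against depth, the feature missing from 1 library, and the share of neurons. With SNCA-GR alone in the 5 libraries that list it the log2 difference was -1.176, and within neuron-like nuclei it was -1.3133. Both lay further from 0 than the bound of 0.3, which argues against the missing feature and the share of neurons as causes. With all libraries thinned to 1 total the difference was -1.0029, also beyond that bound. Random thinning keeps each gene's expected share of UMIs, so this test could not have brought the difference within the bound and decides nothing on depth. Which neurons make up each region remains as an explanation, since dopaminergic-like neurons of SNc-VTA held 42.0 CPM and its other neuron-like nuclei 9.37 CPM, against 33.5 CPM in granule-like neurons of the olfactory bulb.

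The barcodes of the SNc-VTA library of M9376 in 5 clusters of its own made up 52.1% of its kept nuclei. In the largest, of 9037, the ratios of 7 marker sums to the rest of the library ran from 0.777 to 2.14, the highest 2.7532 times the lowest and under the bound of 3, which is consistent with droplets that hold free RNA, and its median of 1175 UMIs, below the 2436 of the rest, argues against doublets. The second, of 1977, stood at 2.9244, close to the bound, with dopaminergic markers at 2.55 times the rest and SNCA at 34.5 against 14.2 CPM, so it may hold dopaminergic nuclei as well. The other 3, of 178, 90 and 35, stood at 5.0681, 182.49 and 39.889, which argues against such droplets there, and the last 2 held astrocyte markers at 8.57 and precursor markers at 5.01 times the rest. Their median UMIs of 9264, 4333.5 and 4913 lay above the rest, so doublets stay open for these 3.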

How the results depend on the processing

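The alternatives with one-library clusters left out, further neuron clusters, the free-RNA level, named nuclei as denominator and SNCA-GR alone were chosen after seeing the data, and all others before. Over 161 alternatives to the counts of genes, lists and classes, the SNCA differences and the dIRE share, 125 kept the direction and the side of the threshold or a count within 1.5 times, 6 were weaker, 30 moved and 0 reversed, while 1 alternative to a single class share and 2 to single isoforms reversed. The counts ranged from 9757 to 12023 genes over all nuclei and from 9111 to 11673 in neurons, the classes passing from 8 to 10, the SNCA difference between regions from -1.1852 to -0.8941 and that of dopaminergic-like neurons from 2.1825 to 2.3686. For single named genes, 2313 of 2363 alternatives were the same over all nuclei, 2355 of 2425 in neurons, 1091 of 1182 in astrocytes and 465 of 592 in oligodendrocytes, and 0 reversed. DESeq2 called 899 genes in astrocytes, 159 in oligodendrocytes, 88 in precursors and 81 in microglia. UMI sums thinned to 1 depth gave 722, 121, 147 and 107, and 337 for the interaction, and nuclei thinned to 1 number gave 674, 36, 125 and 97, where fewer genes were tested. Without the mouse block the counts were 35 in oligodendrocytes, 122 in microglia and 393 for the interaction, and the mitral/tufted SNCA difference was 0.2674 and did not pass. Without the block 16 lists passed, those of the report and 4 more: oligodendrocyte precursor, telencephalic astrocyte, GABA transmission and ependymal and choroid plexus genes. Some single named genes also did not pass without the block. In microglia, no low-count filter gave 395, at least 1000 genes per nucleus 92 and doublets kept 414, and doublets kept gave 426 in precursors. The microglia calls changed with doublets kept: 155 of the 250 stayed, 3 of them in the opposite direction, and 14 of the 250 had the opposite sign. With genes at the free-RNA level left out, 1257 stayed in astrocytes, 252 in oligodendrocytes, 174 in precursors and 184 in microglia. Camera with an estimated correlation, which had few residual degrees of freedom and could hardly call a list, called 0 lists and fry 21. The mitral/tufted SNCA difference did not pass in DESeq2 (0.2377) or on thinned sums (0.3388), nor that of olfactory bulb neurons on thinned sums (0.1514). Beyond thinning and filters, the cause was not tested.

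Leaving out each mouse in turn gave 9780 to 10819 genes over all nuclei, 9186 to 11297 in neurons, 1095 to 1492 in astrocytes, 164 to 313 in oligodendrocytes, 188 to 211 in precursors, 102 to 229 in microglia, 259 to 558 for the interaction, 13 to 17 lists and 8 to 10 classes. For SNCA it gave -1.1852 to -0.8941 between regions, 2.1825 to 2.3217 for dopaminergic-like, 0.236 to 0.2642 for mitral/tufted-like neurons, -0.8203 to -0.4106 for neurons of SNc-VTA and 0.8663 to 1.2792 for those of the olfactory bulb, and 3.4478 to 4.2451 percentage points for dIRE. The microglia-like share was larger and passed with at least 1000 genes per nucleus (1.988), with named nuclei as denominator (1.2047) and without M9376 (1.074), and reversed to -0.7877 with TMM over classes, where it passed (adjusted p = 0.00278). The dIRE4 difference reversed to -0.25102 without M9377 and was 0.34964 without M9378, and the cause was not tested. That of IRE reversed to 1.4232 with the SNCA read count as denominator. In M9377 and M9378 the assigned total was 1.19 and 1.13 times that count in SNc-VTA and 1.08 and 1.09 times in the olfactory bulb. The changed sign of IRE follows from these unequal ratios, and why they differ was not tested. With dIRE counted over that denominator the difference was 5.7673, and the sign-flip within mice as block or pairing left dIRE at 3.8464. The alternatives for endothelial-like nuclei were not run, since that comparison was not made. The thinned sums of the 4 glial classes held 141337 to 274891 UMIs per library, against 19688820 in neurons.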

Other observations

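Among the cell types that the authors named in the long-read table, the share of dIRE reads differed between some types of a region, in 1 mouse or in both. Each was set against the other cell types of its library by Fisher's exact test, two-sided and adjusted over 68 tests. In SNc-VTA, oligodendrocyte precursors showed 63.4% (26 of 41, adjusted p = 2.01e-07) in M9377 and 38.7% (12 of 31, adjusted p = 0.0734) in M9378, and astrocytes 57.1% (8 of 14, adjusted p = 0.0180) in M9377 and 54.2% (13 of 24, adjusted p = 0.00277) in M9378. Dopamine neurons showed 23.8% (123 of 517, adjusted p = 0.463) in M9377 and 30.7% (63 of 205, adjusted p = 0.00593) in M9378, and GABA neurons 19.9% (112 of 563, adjusted p = 0.205) in M9377 and 20.04% (113 of 564, adjusted p = 0.361) in M9378. For dIRE1 alone the GABA type was lower than the other types, at 11.01% (62 of 563, adjusted p = 2.78e-05) in M9377 and 12.6% (71 of 564, adjusted p = 8.53e-04) in M9378. The authors' types cover all 7382 and 6176 nuclei of these libraries and name no neurons there but dopamine and GABA. Their GABA type held 2594 and 2229 nuclei, against 1074 and 831 GABAergic-like and 734 and 742 glutamatergic-like nuclei by the fixed markers. It cannot be taken as GABA neurons alone. Oligodendrocytes showed 20.7% (189 of 913, adjusted p = 0.224) in M9377 and 20.02% (168 of 839, adjusted p = 0.201) in M9378, and endothelial cells 2.78% (1 of 36, adjusted p = 0.00832) in M9377 and 13.4% (13 of 97, adjusted p = 0.0998) in M9378. Microglia showed 52.9% (9 of 17, adjusted p = 0.0193) in M9377, and 0 of 5 in M9378, which allows up to 43.4%. Microglia of the olfactory bulb had 0 of 23 and 0 of 6, which allow up to 14.3% and 39.0%, and did not pass (adjusted p = 0.0686 and 0.658). The GABA_1 neurons, the type with the most reads there, showed 17.2% (311 of 1808, adjusted p = 0.283) in M9377 and 16.2% (299 of 1841, adjusted p = 0.00714) in M9378. In the olfactory bulb, olfactory ensheathing cells showed 45.3% (24 of 53, adjusted p = 3.62e-05) in M9377 and 42.9% (6 of 14, adjusted p = 0.0742) in M9378, and the GABA_2 neurons 19.5% (48 of 246, adjusted p = 0.641) in M9377 and 38.6% (129 of 334, adjusted p = 6.69e-19) in M9378. The GABA_3 neurons showed 13.7% (55 of 401, adjusted p = 0.0488) in M9377 and 10.5% (30 of 285, adjusted p = 0.00194) in M9378, and the mitral and tufted neurons 19.6% (94 of 480, adjusted p = 0.443) in M9377 and 14.7% (61 of 415, adjusted p = 0.111) in M9378. Astrocytes of the olfactory bulb showed 25.5% (27 of 106, adjusted p = 0.113) in M9377 and 19.5% (15 of 77, adjusted p = 0.800) in M9378. The high share of astrocytes in SNc-VTA was thus not seen there, on more reads. Oligodendrocytes of the olfactory bulb showed 17.5% (20 of 114) in M9377 and 20.5% (17 of 83) in M9378 and passed in neither mouse. Assigned reads per nucleus were 1.14 and 1.35 in dopamine neurons and 0.217 and 0.253 in the GABA type of SNc-VTA, and 0.0235 and 0.0374 in its astrocytes. In astrocytes of the olfactory bulb they were 0.459 and 0.368. Reads are taken as independent molecules, so these tests cover counting error only.

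The lists that did not pass over all nuclei gave these counts of members in SNc-VTA against the olfactory bulb, with the counts adjusted over the list alone and the adjusted p of camera in brackets. Among neuronal lists the GABA transmission genes gave 2 higher, 5 lower and 2 not passing (alone 2 and 5; adjusted p = 0.0566). The synuclein and synaptic vesicle genes gave 4 higher, 9 lower and 0 not passing (alone 4 and 9; adjusted p = 0.103). The pacemaking and calcium channel genes gave 4 higher, 6 lower and 1 not passing (alone 4 and 7; adjusted p = 0.200). The serotonin and cholinergic neuron genes gave 2 higher, 0 lower and 1 not passing (alone 2 and 0; adjusted p = 0.311). The cortex and hippocampus excitatory neuron genes gave 1 higher, 4 lower and 2 not passing (alone 1 and 4; adjusted p = 0.187). Among glial and vascular lists the oligodendrocyte precursor genes gave 6 higher, 1 lower and 1 not passing (alone 6 and 1; adjusted p = 0.0705). The astrocyte genes gave 4 higher, 3 lower and 1 not passing (alone 4 and 3; adjusted p = 0.630), and the telencephalic ones 2 higher, 6 lower and 0 not passing (alone 2 and 6; adjusted p = 0.0604). The microglial activation genes gave 3 higher, 2 lower and 4 not passing (alone 3 and 2; adjusted p = 0.261), and the vascular genes 5 higher, 1 lower and 4 not passing (alone 6 and 1; adjusted p = 0.261). The ependymal and choroid plexus genes gave 4 higher, 0 lower and 2 not passing (alone 4 and 0; adjusted p = 0.0632). The mitochondrially encoded genes gave 2 higher, 1 lower and 8 not passing (alone 2 and 1; adjusted p = 0.715). The cytoplasmic ribosomal protein genes gave 4 higher, 0 lower and 10 not passing (alone 3 and 0; adjusted p = 0.294) and the haemoglobin genes 0 higher, 0 lower and 5 not passing (alone 0 and 0; adjusted p = 0.296). Without the mouse block 4 of these lists passed, with adjusted p = 0.0447 for the precursor, 0.0447 for the telencephalic astrocyte, 0.0447 for the GABA and 0.0451 for the ependymal list in camera. Among their members, Syt1 stood at -1.37 ± 0.12, Gad1 at -3.45 ± 0.09, Kcnn3 at 1.42 ± 0.12, Gfap at -1.10 ± 0.23 and Flt1 at 2.22 ± 0.59.

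Of the rarer long-read forms, dIRE5 made up 0.652% of reads in SNc-VTA and 0.127% in the olfactory bulb (adjusted Fisher's exact p = 1.86e-04 in M9377 and 0.163 in M9378), and dIRE7 0.241% and 0.0708% (1.00 and 0.00417). The dIRE6 form had 1 read in SNc-VTA and 3 in the olfactory bulb.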
